A study of Mus musculus with 2 samples.

How the data were processed

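Gene expression was measured by RNA sequencing in pancreatic islets of mice aged 7 months, per the labels, with 1 library from a floxed control mouse genotype and 1 library from the same floxed genotype carrying Cre recombinase under the insulin 2 promoter. The second genotype is called the Srsf2 beta cell knockout here. RNA was extracted with Trizol and libraries were made with a Lifetech protocol, per the labels' protocols. The series' design text names an Illumina NovaSeq sequencer. How many mice gave each library, their sex, and which exons of Srsf2 were floxed are not given in the sources used here.

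Read counts per gene were deposited for both libraries as whole numbers, per the file headers. FPKM values (reads scaled to gene length and to the library's total) were deposited beside them. Recomputing them from the reads, the listed gene length and the total of reads on listed genes gave every deposited FPKM value. The authors' deposited table of the comparison holds normalised counts as a signal per library, which are the read counts divided by 1 size factor per library (1.23 for the control and 0.816 for the knockout). That table also holds the authors' fold ratio of knockout over control, its log2 value, and a p-value with its adjusted form. Per the submitters' processing notes, Bowtie2 2.4.2 and DESeq (version not given in the sources used here) were used, with the builds named mm10 and GRCm38. The counting tool, strand setting, annotation release and treatment of reads shared between gene copies are not given in the sources used here. The table lists 23652 genes with coordinates on RefSeq chromosomes of GRCm38. By symbol, 21455 of them matched the RefSeq gene table of the same assembly, and 20740 of these had the same start and end.

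The libraries held 17412828 (control) and 15098659 (knockout) reads on listed genes, and 16528 genes had at least 1 read in either. Groups came from the labels and columns were matched to samples by their labels. The design had assumed FPKM values, and raw counts were found too. A count model such as that of edgeR needs replicates to estimate the spread, so none was fitted, and no p-value or standard error across samples was computed. The difference of a gene was log2(FPKM + 0.5) in the knockout minus that in the control, over the 10666 genes with a mean FPKM of at least 1. This scale understates differences of low genes. Fold values are ratios of FPKM without the pseudocount. Their 95% counting intervals are exact conditional binomial (Clopper-Pearson) intervals of the read counts. They cover counting error only, since reads without molecular identifiers are not independent molecules, and leave out all variation between mice. A size rule of 2-fold (1 on the log2 scale) takes the place of a test. The median difference of all measured genes was -0.36, and relative differences are differences minus this median.

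Before the data were examined, 30 gene lists were fixed: SR proteins, hnRNP and other splicing regulators, beta cell hormones and identity, alpha cell markers, delta and PP cell markers, secretory granule and exocytosis, beta cell disallowed genes, dedifferentiation and endocrine progenitor, unfolded protein response, p53 targets, senescence and secreted inflammatory factors, proliferation, interferon response, antigen presentation, nuclear OXPHOS, mitochondrial encoded, ribosomal proteins, oxidative stress defence, hypoxia and glycolysis, immediate early and heat shock, lactogen response, markers of acinar, duct, endothelial, stromal, macrophage, lymphocyte, Schwann and neural, and adipocyte and blood cells, and housekeeping genes. A few genes stand in more than 1 list, among them Prlr, Ldha, Sox9, Pdgfra, Birc5 and Rplp0. A list with at least 3 measured members was described by its median and by the percentile of that median among 10000 random lists of the same size matched on mean FPKM in 20 bins. Below 2.5 or above 97.5 it was taken to stand apart. The 13 genes of the mitochondrial encoded list were not analysed here, nor were Mx1, Mx2, Ighm and Igkc.

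Named genes followed a rule fixed at the same time. It took Srsf2, the 10 genes Ins1, Ins2, Gcg, Sst, Ppy, Mafa, Pdx1, Nkx6-1, Ucn3 and Slc2a2, and up to 4 members of each list that stood apart. It also took the 10 genes with the largest difference in each direction at a mean FPKM of at least 5, without unnamed gene models and pseudogenes. List members were ranked in the direction in which the list departed from its random lists. Of the 96 genes that qualified, not all are named, a few because they are not reported here, and other list members named beside them were chosen after their values were seen.

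Alternatives were pseudocounts of 0.1 and 1 FPKM, scaling by the median ratio, by the total without the 20 highest genes and by the authors' normalised counts, no minimum or a mean FPKM of at least 5, leaving out the acinar list, a 1.5-fold rule, and random lists matched in 10 bins. Removal of the length trend (medians of 20 length bins), random lists matched on FPKM in 5 bins and length in 10 bins, and rescaling by the total without the acinar list were added after seeing the data. Intervals of rank correlations across genes come from 1000 bootstrap draws of genes, which are not independent replicates. GC content was taken from the transcripts of a GENCODE annotation by gene symbol, for 10507 of the 10666 genes.

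The calculation was tested on simulated data, with reads drawn for all 23652 genes at the depths of these libraries. Both simulated libraries came from 1 pooled profile with counting error only, without variation between mice or preparations and without a length trend. Simulated lists were random genes, not genes that vary together. The rates below thus describe counting error and are not error rates of the rule or the percentiles for real islets. In the simulated knockout against control comparison, 10658 genes passed the minimum, and 50 genes were planted at each of 4 folds. The 2-fold rule found 100% of those planted at 4.0-fold, 90% at 0.25-fold, 30% at 2.0-fold and 20% at 0.5-fold, and it took in 1 of 10464 unchanged genes. Coverage of the counting interval was computed only for the first part of the unchanged genes in listed order, and it held the true ratio for 95.4% of these. Of 200 unchanged lists 3.5% fell outside the percentiles, and 100% of 20 lists of 15 genes shifted by 0.5 (log2) were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.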

Results

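The study profiled the transcriptome of pancreatic islets, the small endocrine organs that hold insulin-producing beta cells and the glucagon, somatostatin and pancreatic polypeptide cells around them. Islets came from mice aged 7 months. One group was floxed at Srsf2, and the other carried in addition Ins2-Cre, a recombinase driven by an insulin promoter, which deletes floxed sequence in beta cells. Each group had 1 library. The control library held 17412828 reads on genes and the knockout library 15098659. The question posed by the design is how the islet transcriptome differs when beta cells lack Srsf2, also known as SC35, a serine/arginine-rich protein that binds exons and guides splicing. With 1 library per group no difference below has a replicate check, and each describes these 2 libraries, not the genotypes. Counts of genes past 2-fold are as deposited, unless given as relative to the median of all genes, and use the log2(FPKM + 0.5) scale, on which low genes need more than a 2-fold ratio.

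Srsf2 itself was lower in the knockout library. The gene lies on chromosome 11 from 116849897 to 116853675, on the minus strand, in the GRCm38 coordinates of the deposited table, which gives it a length of 3543 bases. It had 2296 reads in the control and 1209 in the knockout, or 37.2 and 22.6 FPKM, a ratio of 0.607 (95% counting interval 0.566 to 0.651). The log2 difference was -0.71. Many genes shifted the same way, with a median of -0.36 over the 10666 measured genes (a ratio of 0.778), and relative to this median Srsf2 differed by -0.34. The authors' deposited table, scaled by size factors, gives a log2 fold change of -0.34 for Srsf2. Of all measured genes 20.2% had a lower difference than Srsf2, and of the 177 genes most like it in level and length 27.1% did. The target was thus lower, in the direction of the labels, by an amount common among other genes. The counts cover the whole gene and all islet cells, including those without Cre.

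The largest difference between the libraries was in digestive enzyme genes of acinar cells, the exocrine cells that surround islets. All 25 measured genes of the acinar list were at least 2-fold higher in the knockout library, with a median log2 difference of 3.16 and a relative median of 3.53 (percentile 100 of the random lists). The list took 1.90% of all reads in the control library (exact binomial 95% interval 1.896% to 1.909%) and 16.5% in the knockout library (16.52% to 16.56%). Pnlip, which encodes pancreatic lipase, stood at 1248 and 11635 FPKM, and Cpa1, encoding carboxypeptidase A1, at 948 and 7556 FPKM. Clps, which encodes the lipase cofactor colipase, had the largest difference of any gene named here, from 8.14 to 357 FPKM, a ratio of 43.8 (counting interval 35.0 to 55.6). Amy2b, a pancreatic amylase, was 18.3-fold higher (17.0 to 19.7). Zg16, a zymogen granule protein, was 12.0-fold and Rnase1, a secreted ribonuclease, 11.3-fold higher. Among genes with a mean FPKM of at least 5, those of the 10 largest higher differences on the log2(FPKM + 0.5) scale outside the list were of the same exocrine kind or of the Reg family of secreted lectins: Reg3d (17.2-fold), Amy2a3 (14.2-fold), Reg3a (27.7-fold, on 7 control reads), the trefoil peptide gene Tff2 (12.9-fold) and the kallikrein gene Klk1 (11.2-fold). Reg1, a list member, was 11.1-fold higher. Amylase, trypsinogen and Reg genes have near-identical copies, and how shared reads were assigned is not given, so values of single copies are uncertain.

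Insulin transcripts kept a similar share of the library, while a set of genes for glucose sensing and hormone receptors of beta cells was much lower. Ins1 and Ins2, the mouse insulin genes, together took 19.5% of reads in the control and 17.8% in the knockout. Of the 29 measured genes of the beta cell list, 8 were at least 2-fold lower and 0 at least 2-fold higher, or 5 and 0 relative to the median of all genes. The lower genes were Glp1r, the receptor for the incretin GLP-1 (68.9 and 16.8 FPKM), the prolactin receptor gene Prlr (11.1 and 3.07), Sytl4, which encodes the granule docking protein granuphilin (64.5 and 20.2), Slc2a2, the glucose transporter GLUT2 (277 and 98.8), the fatty acid receptor gene Ffar1 (45.0 and 16.8), the islet glucose-6-phosphatase gene G6pc2 (1744 and 681), the endoplasmic reticulum oxidase gene Ero1lb (365 and 155) and the granule zinc transporter gene Slc30a8 (494 and 214). Glp1r on chromosome 17 (30901867 to 30936510) had the lowest ratio of them, 0.244 (counting interval 0.218 to 0.273), and Slc2a2 on chromosome 3 (28697903 to 28728361) had 0.357 (0.344 to 0.370).

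Other beta cell genes differed less. The transcription factor genes Nkx6-1, Mafa and Pdx1 had relative differences of -0.41, -0.37 and -0.14, with 5169 and 2618, 7149 and 3715, and 2501 and 1526 reads in control and knockout. Ins2 stood at 231507 and 225483 FPKM and Ins1 at 100413 and 77674 FPKM. The sign for the insulin genes depends on the scaling: Ins2 differed by -0.04 as deposited and by 0.33 relative to all genes, and Ins1 by -0.37 as deposited and by 0.01 with the authors' scaling. Both are short transcripts, and with the length trend removed Ins1 differed by -0.66 and Ins2 by -0.33. On that scale Nkx6-1 differed by -0.66, Mafa by -0.40 and Pdx1 by -0.36, so the insulin genes did not stand clear of these factors. Ucn3, which encodes urocortin 3, a peptide of mature beta cells, stood at 345 and 389 FPKM, a relative difference of 0.53. The median of the beta cell list was -0.50, or -0.14 relative to all genes, at percentile 0 of the random lists. Matched also on transcript length it stood at percentile 1.72. Genes of secretory granules and exocytosis had a relative median of -0.27 (25 measured, 2 at least 2-fold lower as deposited and 0 relative to all genes, percentile 0.005), led by the calcium channel gene Cacna1d (-0.96), the vesicle priming gene Unc13a (-0.68) and Syt13 (-0.57), and with length matched as well that list no longer stood apart (percentile 4.24).

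**Figure D1:**
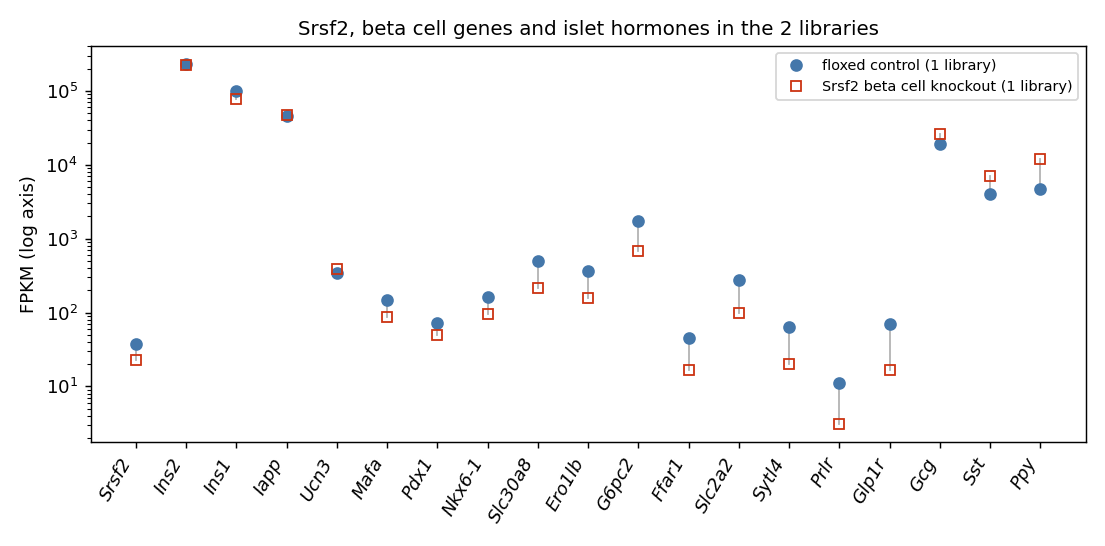
FPKM (log axis) of Srsf2, beta cell genes and the other islet hormones in the control library (filled circles) and the knockout library (open squares), 1 library each, so no error bar is drawn. Slc2a2 stands at 277 and 98.8 and Glp1r at 68.9 and 16.8, while Ins2, at 231507 and 225483, nearly overlaps.

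Hormones of the other endocrine cells were higher in the knockout library. Ppy, which encodes pancreatic polypeptide, was 2.54-fold higher (counting interval 2.51 to 2.57), from 4676 to 11857 FPKM. Its neighbour Pyy, encoding peptide YY, was 2.27-fold higher, and Sst, encoding somatostatin, 1.71-fold higher at 4063 and 6967 FPKM. The delta and PP cell list had a relative median of 1.43 over 5 measured genes, 3 of them at least 2-fold higher as deposited and 4 relative to all genes (percentile 99.8, and 94.9 at a mean FPKM of at least 5). Gcg, the glucagon gene of alpha cells, was 1.38-fold higher at 18915 and 26029 FPKM. The alpha cell list had a relative median of 0.45 over 9 genes, 0 of them past 2-fold as deposited and 1 relative to all genes, with Slc38a5, an amino acid transporter gene, highest at 1.25 and Gria3 lowest at -0.58 (percentile 97.97, and 95.97 with length matched, where it no longer stood apart). In the same library the acinar list took 16.5% of reads against 1.90%.

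Genes encoding the splicing machinery leaned lower, though not beyond random lists once the length trend was removed. Of 12 measured SR protein genes, the family of Srsf2, 0 were past 2-fold in either direction, and their relative median was -0.32 (percentile 0.31, 0.83 with length matched and 3.47 with the length trend removed). Tra2b differed by -0.58, Srsf4 by -0.54, Srsf7 by -0.49 and Srsf5 by -0.37 relative to all genes, while Srsf9 differed by 0.36. The hnRNP and other splicing regulators had a relative median of -0.18 over 24 genes, 3 of them at least 2-fold lower as deposited and 1 relative to all genes. Snrnp70, a protein of the U1 particle that recognises 5' splice sites, was the lowest at 3635 and 1035 reads (ratio 0.328, counting interval 0.306 to 0.352), followed by Hnrnph1 and Sf3b1 with ratios of 0.479 and 0.480. This second list stood at percentile 0.71, and at 44.1 once random lists were matched on length too, so its lower level did not set it apart from other long genes.

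Among genes with a mean FPKM of at least 5, leaving out unnamed gene models and pseudogenes, the 10 with the lowest differences on the log2(FPKM + 0.5) scale had varied functions. Abhd2, a lipid hydrolase gene on chromosome 7, had 859 control reads and 64 knockout reads (ratio 0.0859, counting interval 0.0656 to 0.111). Kcnf1, a potassium channel subunit gene, had a ratio of 0.126 (0.101 to 0.156). Ern1 encodes IRE1, a sensor of unfolded protein in the endoplasmic reticulum, and had 28.0 and 4.68 FPKM (ratio 0.167, 0.147 to 0.190). P2ry1, a purinergic receptor gene, had 0.204, Megf9 0.207, the small GTPase gene Rab31 0.232, Mdm1 0.241, Usp51 0.241 and Il6ra, the interleukin 6 receptor gene, 0.244, and Glp1r completed this group. Their relative log2 differences ran from -2.79 for Abhd2 to -1.59 for Usp51.

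Stress lists did not move as a block. The unfolded protein response list had a relative median of 0.24 over 32 genes and stood at percentile 73.3. Beside Ern1, the chaperone gene Hyou1 was lower (relative -0.66), whereas Atf3, a stress transcription factor gene, was 6.17-fold higher (counting interval 4.26 to 9.19, 34 and 182 reads), and Derl3 and Eif4ebp1 were 2.21-fold and 2.17-fold higher. The p53 targets had a relative median of -0.05 (18 genes, percentile 31.8), with Cdkn1a, the cell cycle inhibitor p21, at -0.01. Senescence and secreted inflammatory factors (8 genes, 0.18, percentile 86.5) and proliferation genes (5 genes, 0.02, percentile 54.5, but 99.5 with no filter on low values) did not stand apart either. Oxidative stress defence (19 genes, 0.37, percentile 92.8, but 98.8 at a mean FPKM of at least 5), hypoxia and glycolysis (18 genes, -0.00, percentile 16.8), nuclear OXPHOS (29 genes, 0.35, percentile 85.6), lactogen response (6 genes, -0.10, percentile 33.6) and housekeeping genes (12 genes, 0.22, percentile 54.3) were likewise within the range of random lists. Immediate early and heat shock genes stood above it with a relative median of 0.63 (13 genes, percentile 99.98), led by Ier3 at 1.23 and Ier2 at 1.17, with 0 genes at least 2-fold higher as deposited and 3 relative to all genes. Acinar, lymphocyte and macrophage markers were higher in the same library.

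Among immune and other non-endocrine lists, leaving out the acinar list, lymphocyte markers were the clearest to be higher in the knockout library. Of the interferon, antigen presentation, stromal, endothelial and Schwann lists 0 genes were at least 2-fold higher as deposited. Values per list are relative to all genes. Of 6 measured lymphocyte markers 5 were at least 2-fold higher, with a relative median of 1.65 (percentile 100): the B cell genes Ms4a1 (28 and 170 reads), Cd79b (35 and 104) and Cd79a (358 and 770), with Cd52 and Coro1a. Macrophage markers had a relative median of 0.73 (13 genes, 2 at least 2-fold higher, percentile 100, and 98.98 with length matched). With the length trend removed their median was 0.28. Cd68 stood at 1.45 and Cd53 at 1.43, while Csf1r stood at -0.14 (260 and 151 reads). Antigen presentation genes had 0.80 (8 genes, percentile 99.89, and 97.3 with the length trend removed), with Cd74 at 0.94 and B2m at 0.90. Interferon response genes had 0.34 (14 genes, percentile 99.72, 93.3 with length matched and 82.3 at a mean FPKM of at least 5), with Gbp2 at 1.29 and Rsad2 at -0.54. Duct markers had 0.50 (9 genes, percentile 98.3, 90.0 with length matched and 80.9 at a mean FPKM of at least 5), where 2 genes, Tff2 and Muc1, were past 2-fold as deposited and 3 relative to all genes, and Krt7 differed by -0.22. Stromal markers had 0.38 (8 genes, percentile 97.84, 96.89 with length matched and 95.9 with no filter) and endothelial markers -0.04 (12 genes, percentile 33.5). Schwann and neural markers had 0.78 (3 genes, percentile 99.0, and 96.4 with no filter), and adipocyte and blood cell markers 1.18 (4 genes, all globin genes, percentile 99.97, 96.55 with length matched and 66.2 with no filter).

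Beta cell disallowed genes, which most tissues use and beta cells keep low, had a relative median of 0.67 over 16 genes (percentile 100). Arhgdib, a gene common in blood cells, was past 2-fold (91 and 178 reads), Mgst1 had a ratio of 2.09 on 21 and 38 reads but was past 2-fold with the pseudocount only relative to all genes (3 genes of the list were), Zfp36l1 had a ratio of 1.69, and the lactate dehydrogenase gene Ldha had 232 and 202 reads, a relative log2 difference of 0.37. In dedifferentiation and endocrine progenitor genes the relative median was 0.49 over 8 genes (percentile 99.57, and 94.65 with the length trend removed). Neurog3, the endocrine progenitor factor, had 6.23 and 9.25 FPKM and Aldh1a3, an enzyme gene used as a mark of dedifferentiated beta cells, 4.29 and 6.04 FPKM, while Sox4 was at least 2-fold lower (relative -1.28). Ribosomal protein genes had a relative median of 0.87 over 30 genes (percentile 100), with Rpl32 highest at 1.35, and 0 of the 30 were past 2-fold as deposited and 7 relative to all genes. These lists were higher in the library in which acinar, lymphocyte and macrophage markers were also higher.

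**Figure D2:**
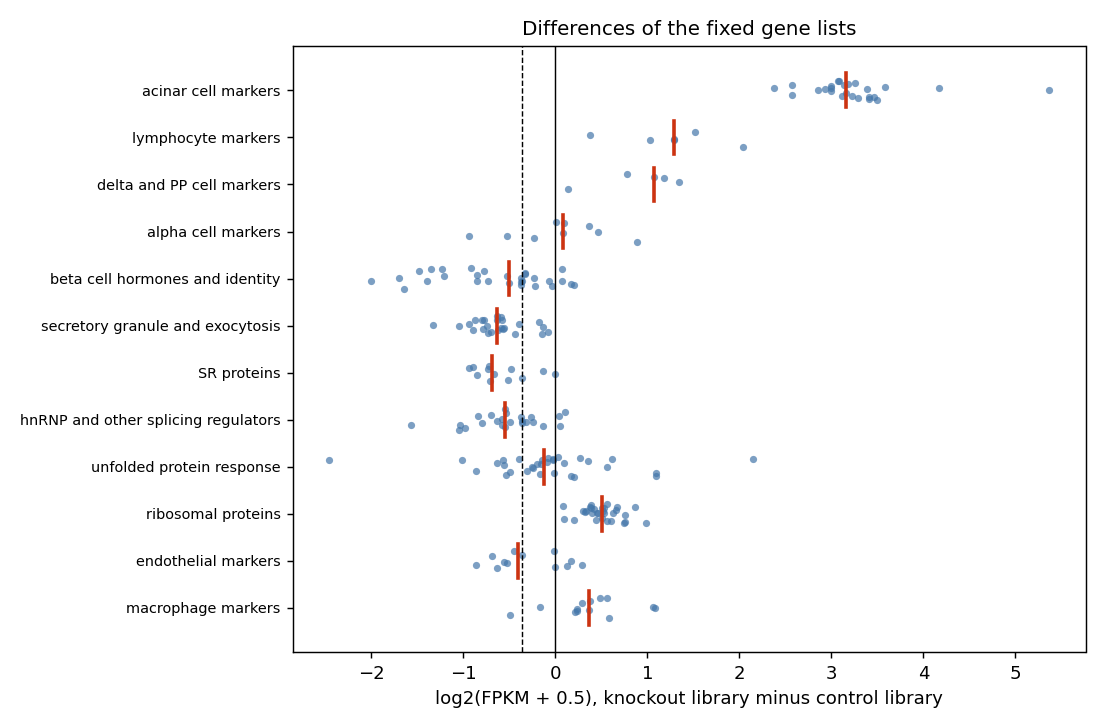
Difference between the libraries on the log2(FPKM + 0.5) scale, knockout minus control, for measured genes (points, spread vertically for legibility) of 12 fixed lists, with list medians as red bars and the median of all genes, -0.36, as a dashed line. The acinar list stands at a median of 3.16 and the delta and PP cell list at 1.07, while the SR protein list lies at -0.69.

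Over all 10666 measured genes, 167 (1.57%) were at least 2-fold higher and 674 (6.32%) at least 2-fold lower in the knockout library. This split depends on the scaling. Of the genes past 2-fold, 19.9% were higher as deposited and 70.3% were higher once the median of all genes was set to 0 (343 higher and 145 lower). Of the 29 lists with enough measured genes, 19 stood apart from their random lists, 15 above and 4 below. In the authors' deposited table, which compares 1 library with 1 library by DESeq, 82 of 16528 genes had an adjusted p-value under 0.05, and 72 of these were higher in the knockout, 25 of them in the acinar list and 0 in the beta cell list.

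The difference also followed transcript length. Across genes the Spearman rho of length and log2 difference was -0.55 (bootstrap interval -0.56 to -0.53). The 1067 shortest genes, of 206 to 1323 bases, had a median of 0.17, and the 1066 longest, of 8432 bases and more, a median of -0.63. GC content had a rho of 0.03. Of the lists that stood apart, 12 still did so against random lists matched on length too, among them the acinar, lymphocyte, delta and PP cell, beta cell, SR protein, ribosomal protein and disallowed gene lists.

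**Figure D3:**
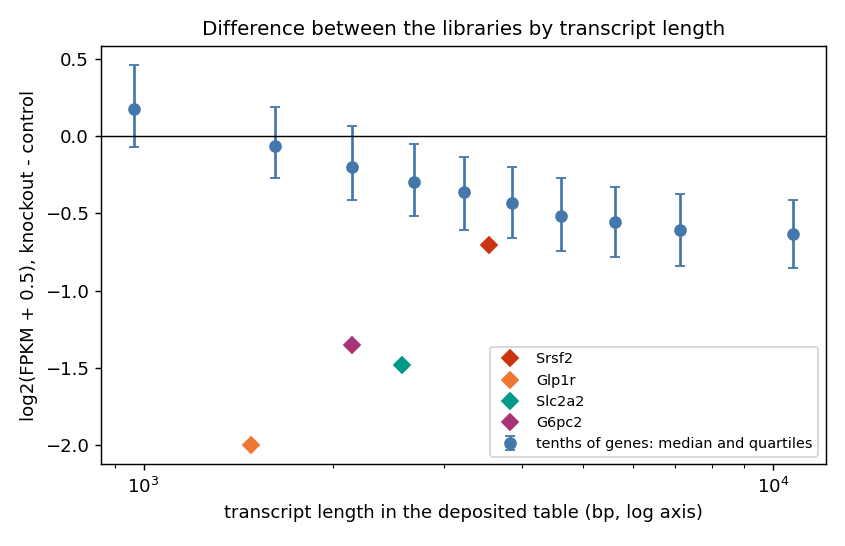
Median log2 difference (knockout minus control) of 10 equal groups of genes ordered by transcript length (bases, log axis), with bars from the lower to the upper quartile, and Srsf2, Glp1r, Slc2a2 and G6pc2 as diamonds. Medians run from 0.17 in the shortest group to -0.63 in the longest, and Glp1r, Slc2a2 (-1.48) and G6pc2 (-1.36) lie far below genes of their length.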

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

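Removal of the length trend, matching on length and rescaling without the acinar list were chosen after seeing the data. The number of genes at least 2-fold higher in the knockout library, 167, became 343 with median ratio scaling, 258 without the 20 top genes, 426 with the authors' normalised counts, 92 at a mean FPKM of at least 5 and 394 with the 1.5-fold rule. The number of genes at least 2-fold lower in the knockout library, 674, became 145, 335, 273, 408 and 3160 in the same order, 112 with the length trend removed and 278 rescaled without the acinar list. A higher minimum or a smaller fold changes which genes can count. The authors' normalised counts bring another scaling and a pseudocount of 0.5 that weighs less on counts than on FPKM, which were not separated. For the other settings the cause was not tested.

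The difference of Srsf2, -0.71, was -0.34 with median ratio scaling and with the authors' normalised counts, -0.49 without the 20 top genes, -0.48 without the acinar list and -0.31 with the length trend removed. It stayed below 0 under the 7 alternatives run for it. Of the 40 named genes at least 2-fold apart, 0 changed sign under them. Of all 96 named genes 3 did (Ins1, Ins2 and Hbb-bt), and of 672 alternative values 320 moved by more than the counting error. The 0 of 40 was in part set in advance. Median ratio scaling only removes the median of all genes, -0.36, so it could not reverse a 2-fold difference.

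The number of lists that stood apart, 19, was 12 of 25 at a mean FPKM of at least 5, 11 of them among the 19, and 12 of 29 with length matched, all among the 19. It ran from 14 to 19 elsewhere. At a mean FPKM of at least 5, the proliferation, disallowed gene, Schwann and blood cell lists had too few genes left, the alpha cell (94.2), delta and PP cell (94.9), interferon (82.3), duct (80.9) and stromal (93.8) lists no longer stood apart, and oxidative stress defence did (98.8). With no filter, the stromal (95.9), Schwann (96.4) and blood cell (66.2) lists no longer stood apart and proliferation did (99.5). With the length trend removed, the SR protein (3.47), hnRNP (23.4), dedifferentiation (94.65), antigen presentation (97.3) and duct (96.3) lists no longer stood apart, and the cause was not tested. Rescaled without the acinar list, the alpha cell list did not (97.3). Of 343 list percentiles under alternatives, 320 stayed on the same side and 0 crossed to the opposite one. Part of this was fixed in advance, since median ratio scaling moves every gene alike and cannot change a percentile. The other rescalings also move most genes nearly alike. No paired analysis was possible because each genotype had 1 library, so leaving out a replicate could not be tried either. Each alternative fixed before the data were examined was run. Depth limits low genes: at 28 and 170 reads, the ratio of Ms4a1 has a counting interval of 4.68 to 10.9.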

Other observations

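All tests in this part were chosen after the results were seen, and so were the sterol and clock lists and the single genes of the first paragraphs.

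Genes of cholesterol synthesis and uptake were lower in the knockout library. Of 19 measured genes 4 were at least 2-fold lower as deposited, 2 relative to all genes, and 0 at least 2-fold higher, and the relative median was -0.42 (percentile 0.03 of random lists, and 0.02 with length matched). Idi1, the isopentenyl diphosphate isomerase gene, had 238 reads in the control and 42 in the knockout (ratio 0.204, counting interval 0.143 to 0.283). Srebf2, the transcription factor gene that drives this pathway, had a relative difference of -0.79, while Mvd differed by 0.54. Circadian clock genes were lower too, with a relative median of -0.51 over 14 genes (percentile 0, and 0.07 with length matched), of which 5 were at least 2-fold lower as deposited and 0 relative to all genes. Per1 (relative -0.93), Cry2 (-0.87) and Ciart (-0.86) are repressors within the clock, as is Cry1, which differed by 0.46. The hour at which islets were taken is not given in the sources used here. Both lists were lower in the library in which the acinar list took 16.5% of reads, against 1.90% in the control library.

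A few further genes stood out by size, the first 4 of them outside the fixed lists. Fgf21, a stress hormone gene that acinar cells also express, had 6 control and 132 knockout reads (ratio 25.4, counting interval 11.4 to 70.4). Nupr1, a stress gene first described in inflamed pancreas, had 96.2 and 818 FPKM (counting interval of the ratio 7.97 to 9.08). Cxcl13, a chemokine gene that attracts B cells, had 75 and 250 reads, beside the higher B cell genes Ms4a1 and Cd79b. Ghrl, encoding ghrelin, had 27 and 66 reads. Txnip, a glucose-induced gene of beta cells and a member of the oxidative stress list, was 3.74-fold lower (3.63 to 3.86), at 446 and 119 FPKM, and in the same list the metallothionein gene Mt1 was 2.36-fold higher.

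Acinar enzyme genes were higher in the knockout library by a median of 3.16 (log2). Library scaling is argued against as the cause, since it moves every gene alike and the median of all genes was -0.36. The lowest list median under the scaling alternatives was 3.39. Each of these raised the knockout values relative to the control, so none could have lowered the list median. Acinar tissue carried over with the islets is a candidate for most of the list, and 23 of 25 genes lay within 2-fold of its 8.95-fold median. Of the beta cell list 26 of 29 genes lay as close to their own median. This closeness thus cannot tell carried-over tissue from a joint rise of the acinar genes. Of the acinar list 2 genes, Reg1 and Reg2, can also be made by islets. Outside the 2-fold range of the acinar median were Clps, at 5.37, and Amy2b, at 4.17, against a standard deviation of 0.57 across the list. Why they differ was not tested. Whether loss of Srsf2 in beta cells has any part in it stays open with 1 library per genotype, and a control with Cre and no floxed gene was not analysed here.

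Beta cell genes at least 2-fold lower in the knockout library numbered 8 of 29, with a median of -1.44 (SD 0.27 across these genes), where random lists matched on FPKM and length had a median of 2 such genes, at most 5 within their central 95% range and up to 9 in any draw. A smaller share of beta cell RNA, beside the larger acinar share, would lower the abundant beta cell peptides alike, but Ins1, Ins2, Iapp and Ucn3 had a median of 0.02, and with the length trend removed -0.28 against -1.12 (SD 0.41) for the lower genes, a smaller gap. The gap cannot decide whether a smaller beta cell share is the whole cause. The lower genes were taken by their low values, and the peptide set was chosen after the results were seen. With the length trend removed, Nkx6-1 (-0.66), Mafa (-0.40) and Pdx1 (-0.36) lay between the medians of the peptides and the lower genes. A common part remains possible. The list's SD of 0.61, against 0.55 for all genes, does not bear on a shift shared by its genes. The length trend is argued against as the whole cause, as only 0.04% of those random lists (4 of 10000) held as many lower genes as this list. A candidate explanation is loss of Srsf2 in beta cells, which cannot be told apart from differences between individual mice or from an effect of Cre with 1 library per genotype.

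Long transcripts were lower and short transcripts higher in the knockout library across all genes. Loss of genes with a long genomic span is argued against as the cause, as the partial rank correlation of span given transcript length was 0.015, against -0.45 for length given span. A length-dependent difference of RNA quality or library preparation may underlie the trend: within marker lists of non-endocrine cells, which Ins2-Cre is not meant to reach, rho was -0.43 over 51 genes (bootstrap interval -0.64 to -0.17). Without the genes of the acinar list rho was -0.544 over 10641 genes, against -0.546 over all genes. The trend thus did not rest on the listed acinar genes, which were too few among all genes to move rho much. That check does not cover other transcripts of acinar cells, and whether these add to the trend stays open. Measures of RNA integrity were not analysed here, and the trend bears on the splicing regulator and exocytosis lists, whose genes are long.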
